A study of Cavia porcellus with 11 samples.

How the data were processed

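RNA-seq was performed on guinea pig (Cavia porcellus) cochleae in 3 groups: 4 control libraries without treatment, 4 libraries after cisplatin and 3 libraries after cisplatin given together with STB. The series title names Schisantherin B, a lignan of Schisandra, and the labels write the second treatment as STB without spelling it out. Dose, time after treatment, sex and the number of animals or cochleae behind each library were not given in the sources used here. Nothing in the labels states that libraries of a group came from separate animals, so the p-values measure the spread between these libraries, which may be technical.

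Per the labels' protocols, RNA was extracted with a column kit, mRNA was selected on oligo(dT) beads or, as an alternative, ribosomal RNA was removed, and paired-end libraries that keep the strand were made with dUTP. Which of these enrichments each library received was not given in the sources used here. Per the submitters' processing notes, the tools were cutadapt 1.9.1, HISAT2 2.2.1 and HTSeq 0.6.1, with no role stated for any of them. The deposited table, per the file headers, gives for each library a raw count and an FPKM value for each of 21481 genes, and for each gene its exonic length and position. The counts are whole numbers that the authors did not normalize. The FPKM values of the authors follow from these counts: the library total implied by count, exonic length and FPKM was between 0.999999 and 1 of the sum of the deposited count column. FPKM and the deposited exonic length entered no test. The genome build was not given in the sources used here. Of the gene symbols, 21478 were found in the RefSeq gene table of assembly mCavPor4.1, all with identical start and end positions, and 3 were not. Whether counting used the strand was not given in the sources used here, so reads of overlapping genes on opposite strands cannot be told apart. A total of 5273 genes carried only a LOC symbol and could not be matched to the gene lists.

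Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with filterByExpr by group, which left 15384 genes and removed 6097. Library sizes were scaled with TMM factors. A single quasi-likelihood model (glmQLFit with robust estimation, glmQLFTest) was fitted to all 11 libraries with the groups as coefficients and no covariates, and each pair of groups was compared. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and genes with an adjusted p under 0.05 were called. The common biological coefficient of variation was 0.276. CPM values are scaled by TMM library sizes and are given as mean ± SD, and fold changes are fitted log2 values with standard errors (SE).

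The comparisons, the tests, the rule for named genes and 39 gene lists on stress and death pathways, housekeeping programmes and the cell types that a cochlea dissected in its bone can hold were fixed before the data were examined. The lists held 939 genes, of which 823 were in the table by symbol, and 38 lists had at least 3 tested members. Lists were tested with camera (limma 3.58.1) on voom values with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 38 lists, and beside it with an estimated correlation and with fry. Members were also counted at an edgeR p adjusted over the list alone. This adjustment does not account for the number of lists, so it is weaker evidence than a call over all genes. The score of a list is the mean log2 CPM of its members, with a prior count of 2, minus the control mean. The text names CNPY2 and, per comparison, the 10 genes that rose most and the 10 that fell most among genes with an adjusted p under 0.05, a mean of at least 1 CPM in the higher group, a gene symbol other than a LOC symbol, and libraries of both groups that do not overlap (5 and 5 for the combined treatment against control). Where none passed in a direction, up to 5 with the smallest unadjusted p were named and given as values only. For each list described, up to 4 members with the smallest p were named. The lists described are those called and those that bear on cisplatin injury, whatever their result.

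The return toward control was measured with the 4 cisplatin libraries split into pairs. One pair defined the genes and their direction against control, the other was compared with the combined treatment, and the share was averaged over the 6 assignments. The value with no effect came from 5 simulated data sets without group differences. The test was checked on simulated counts with 200 changed genes. For cisplatin against control it recovered 57.0% of 100 genes changed 2-fold and 92.0% of 100 changed 4-fold, and 6.25% of its calls were false. For the combined treatment against cisplatin it recovered 62.0% and 82.0% with 4.61% false, and for the combined treatment against control 54.0% and 83.0% with 8.55% false. A list changed 1.5-fold was called in each of these simulations, and 0 of the 37 other lists was called by camera. Genes were drawn independently there, so the simulations cannot show how often camera calls unchanged lists whose members are correlated. In the real data the estimated correlation for cisplatin against control was 0.876 for cytosolic ribosomal proteins and 0.602 for immediate early genes.

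The alternatives were DESeq2 size factors and upper-quartile scaling in edgeR, DESeq2 1.42.0, limma-voom with sample quality weights, no low-count filter, a filter of mean CPM of at least 1, fits of only the groups compared, a replicate block, stricter thresholds and leaving out each library in turn. A fit with 2 surrogate variables (sva 3.50.0) was added after seeing the data. Library totals ran from 14338894 to 18508296 counts. No libraries were duplicates: the smallest chi-square per degree of freedom between the counts of any pair was 14.8. No library was left out of the tests.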

Results

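Gene expression was measured by RNA-seq in guinea pig cochleae that were untreated, had received cisplatin, a platinum drug whose side effects include hearing loss, or had received cisplatin together with STB. The control group held 4 libraries with 14338894 to 18508296 counts, the cisplatin group 4 libraries with 15987935 to 17250430 and the combined group 3 libraries with 15183801 to 17967896. Coch, which encodes the abundant secreted protein cochlin of the inner ear, took 2.79% to 4.97% of the counts of a library. The first principal component (29.9% of the variance) did not separate the groups, with control replicate 2 and combined replicate 2 at one end and cisplatin replicate 4 at the other. On the second (17.1%) cisplatin replicate 2 lay farthest from the rest. There was no group given STB alone among these samples.

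CNPY2, the gene named in the series title, encodes a canopy family protein of the endoplasmic reticulum. The guinea pig gene Cnpy2 lies at positions 49350385 to 49354027 on the minus strand of its scaffold, in the coordinates of the deposited table. Cnpy2 was at 91.8 ± 8.70 CPM in control (SD, n = 4), 107 ± 4.44 CPM after cisplatin (n = 4) and 97.2 ± 12 CPM after the combined treatment (n = 3). Its log2 fold change was 0.22 (SE 0.11) for cisplatin against control, which did not pass the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.525). For the combined treatment against cisplatin it was -0.14 (SE 0.12, edgeR adjusted p = 0.777), and against control 0.08 (SE 0.12). Of the 3 canopy genes tested, Cnpy4 rose after cisplatin when adjusted over the list alone (log2 fold change 0.67, SE 0.18, edgeR adjusted p = 0.00823 over the list and 0.440 over all genes). For the combined treatment against cisplatin Cnpy4 had a log2 fold change of -0.53 (SE 0.19), with an adjusted p of 0.0535 over the list, and 1 canopy gene fell over the list alone without control replicate 1, control replicate 2 or cisplatin replicate 3. The canopy family was not called by camera for cisplatin against control (adjusted p = 0.0940), but was called without control replicate 1 (0.00795; adjusted p = 0.792 with an estimated correlation) or cisplatin replicate 4 (0.0440; adjusted p = 0.739 with an estimated correlation). Cnpy3 had a log2 fold change of 0.00 (SE 0.16) for cisplatin against control and 0.04 (SE 0.17) for the combined treatment against cisplatin.

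**Figure D1:**
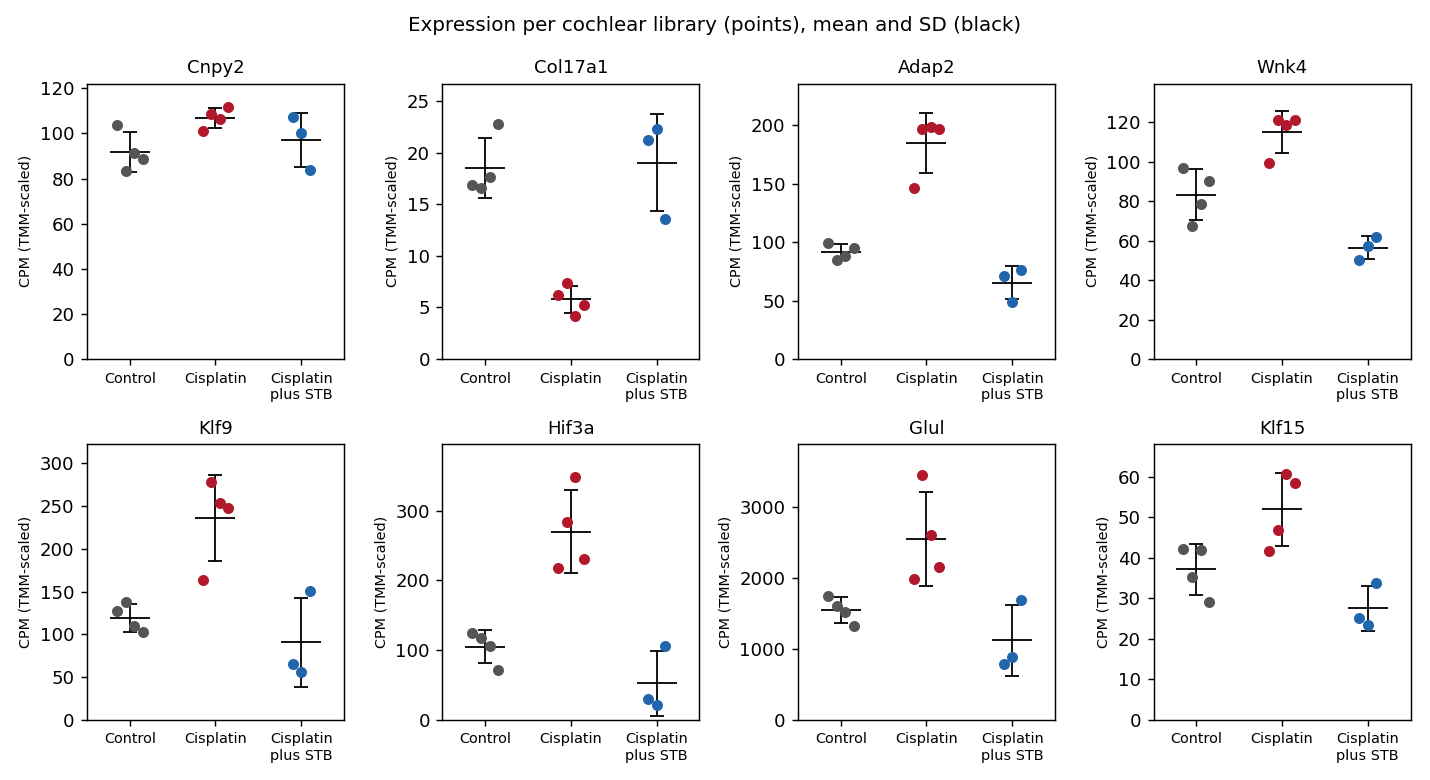
Expression in CPM (TMM-scaled, linear axes) of 8 genes in each library of the control, cisplatin and cisplatin plus STB groups; points are libraries and bars give the mean and SD. The 4 cisplatin libraries lie below all other libraries for Col17a1 and above all others for Adap2, Wnk4, Klf9 and Hif3a, while the groups overlap for Cnpy2.

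Cisplatin-treated cochleae were compared with untreated ones first. The genes with the smallest p that were higher in all 4 cisplatin libraries were Adap2, an Arf GTPase-activating protein (log2 fold change 1.01, SE 0.15), Myo7b, an unconventional myosin (1.83, SE 0.30), F3, tissue factor (1.54, SE 0.28), Prodh, the mitochondrial proline dehydrogenase (1.47, SE 0.29), and Slc30a2, a zinc transporter (1.04, SE 0.22). Among those lower in all 4 were Col17a1, a hemidesmosomal collagen (-1.68, SE 0.22), Matn1, a cartilage matrix protein (-1.96, SE 0.33), Grik4, a kainate receptor subunit (-2.06, SE 0.38), and Myh7b, a myosin heavy chain (-1.03, SE 0.19). Col17a1 was at 18.5 ± 2.91 CPM in control and 5.77 ± 1.35 CPM after cisplatin, and Adap2 at 91.7 ± 6.58 and 185 ± 25.4 CPM. None of these 9 genes passed the adjustment, Col17a1 having the smallest edgeR adjusted p (0.0719). Prodh, Slc30a2 and Myh7b each overlap a gene on the opposite strand. Of 15384 genes, 0 were called by edgeR, against 33 by DESeq2, 3 by limma-voom with sample quality weights and 1 by edgeR with no low-count filter. At an unadjusted p under 0.05 edgeR gave 1494 genes, 682 higher and 812 lower, while other splits of these libraries gave 181 to 1849. The libraries of both groups did not overlap for 6.06% of genes, where the average over all splits is 2.86%. Without cisplatin replicate 1 edgeR called 7 genes, without combined replicate 2 Adap2 alone and without combined replicate 3 Col17a1 alone.

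Of the 38 gene lists, 5 were called by camera for cisplatin against control, all of them higher after cisplatin. As many lists or more were called in 33 of the 35 splits of these libraries, the real one included (highest other 13). Glucocorticoid-responsive genes had a median log2 fold change of 0.73 over 16 tested members (camera adjusted p = 0.000567; adjusted p = 0.667 with an estimated correlation). Adjusted over the list alone, 8 of them rose and 2 fell, and 0 were called by edgeR over all genes. Dusp1, a MAP kinase phosphatase, rose over the list alone (log2 fold change 0.83, SE 0.21), as did Klf9, a Krüppel-like transcription factor (0.98, SE 0.28), while Cdkn1c, a cell cycle inhibitor (-0.39, SE 0.12), and Tat, tyrosine aminotransferase (-1.68, SE 0.55), fell. Without control replicate 3 or cisplatin replicate 2 no member passed over the list alone, and without cisplatin replicate 2 the median was 0.47. Only 1 member rose without control replicate 4, and 3 rose without cisplatin replicate 3, with the camera call kept in each of these fits at the preset correlation (adjusted p = 0.735 to 0.910 with an estimated correlation over the fits that left out 1 library). Immediate early genes had a median of 0.95 over 22 members (camera adjusted p = 0.000567; adjusted p = 0.907 with an estimated correlation), and of these Dusp1 alone rose over the list alone. Fosl1, an AP-1 subunit, had a log2 fold change of 2.72 (SE 0.81). The score of this list was 2.19 in cisplatin replicate 2 and between -0.12 and 0.32 in the other cisplatin libraries, and without that library the call ended (median 0.16, camera adjusted p = 0.279). Without cisplatin replicate 1, 12 of its members rose over the list alone.

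Cytosolic ribosomal proteins (median 0.13, camera adjusted p = 0.000855), antioxidant and NRF2 target genes (median 0.14, adjusted p = 0.0190) and oxidative phosphorylation genes (median 0.09, adjusted p = 0.0391) were also higher by camera, each at an adjusted p = 0.907 with an estimated correlation. No member of these lists passed over the list alone. The members with the smallest p were Rpl6, a protein of the large ribosomal subunit (log2 fold change 0.31, SE 0.14), Fth1, the ferritin heavy chain (0.49, SE 0.19), Gpx3, a secreted glutathione peroxidase (0.89, SE 0.40), and Sdhd, a subunit of succinate dehydrogenase (0.35, SE 0.12). The call of ribosomal proteins was lost without control replicate 2 (0.291), control replicate 4 (0.101) or cisplatin replicate 2 (0.279), and that of antioxidant genes without control replicate 2 (0.0548), control replicate 4 (0.101) or cisplatin replicate 2 (0.352). That of oxidative phosphorylation was lost without control replicate 3 (0.0570), control replicate 4 (0.583), cisplatin replicate 2 (0.279) or cisplatin replicate 3 (0.141), each with its camera adjusted p.

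The p53, unfolded protein response, cell death, inflammatory, interferon and clock lists were not called by camera in the fit of all libraries with the groups alone. The p53 target genes had a median log2 fold change of 0.21 (camera adjusted p = 0.122), with Sesn1, a stress-induced sestrin, at 0.59 (SE 0.19), Spata18, a gene of mitochondrial quality control, at -0.58 (SE 0.20) and Gadd45a, a growth arrest gene, at 0.71 (SE 0.27). They were called without cisplatin replicate 4 (0.0440; adjusted p = 0.739 with an estimated correlation), while without cisplatin replicate 2 their median was 0.07 (camera adjusted p = 0.398). Their score was 0.47 in that library and 0.01 to 0.14 in the other cisplatin libraries. Unfolded protein response genes, which include Cnpy2, had a median of 0.06 (adjusted p = 0.580), with 18 positive and 10 negative. Atf4, the transcription factor of the integrated stress response, stood at 0.49 (SE 0.14), Atf3 at 2.33 (SE 0.94) and Sdf2l1, an endoplasmic reticulum cochaperone, at -0.42 (SE 0.20). Cell death machinery had a median of 0.12 (adjusted p = 0.123), with Mcl1, an anti-apoptotic BCL2 relative, at 0.54 (SE 0.16). Inflammatory mediators had a median of 0.38 (adjusted p = 0.123), with Socs3, a cytokine signalling inhibitor, at 2.61 (SE 1.04). They were called without cisplatin replicate 4 (0.00648; adjusted p = 0.739 with an estimated correlation), while without cisplatin replicate 2 their median was 0.06 (camera adjusted p = 0.913). Interferon-stimulated genes had a median of -0.52 (adjusted p = 0.123), were called as lower without control replicate 2 (0.000539; adjusted p = 0.861 with an estimated correlation) or control replicate 3 (0.00272; adjusted p = 0.858 with an estimated correlation), and had a median of 0.05 without control replicate 4, whose score was 1.29. Circadian clock genes had a median of 0.09 (adjusted p = 0.460).

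Among cell type markers, hair cell markers had a median log2 fold change of 0.02 after cisplatin (camera adjusted p = 0.837), with Pcdh15, a tip link cadherin, at -0.52 (SE 0.26). Spiral ganglion neuron markers had a median of -0.77 (adjusted p = 0.123), which became 0.45 without control replicate 2. They were called as lower without control replicate 1 (0.0227; adjusted p = 0.831 with an estimated correlation), control replicate 4 (0.00532; adjusted p = 0.910 with an estimated correlation) or cisplatin replicate 3 (0.000525; adjusted p = 0.766 with an estimated correlation). The neuron score ran from -1.17 to 1.9 within the control group. Stria vascularis markers had a median of 0.22 (adjusted p = 0.671), which became -0.11 without cisplatin replicate 3. Macrophage markers had a median of 0.15 (adjusted p = 0.719), or -0.03 without cisplatin replicate 2. They were called without cisplatin replicate 4 (camera adjusted p = 0.0109, or 0.739 with an estimated correlation). Among them Cd163, a hemoglobin scavenger receptor, rose over the list alone. Its log2 fold change was 1.5 (SE 0.34, edgeR adjusted p = 0.0164 over the list and 0.440 over all genes). It did not pass without control replicate 1, control replicate 3, cisplatin replicate 2 or cisplatin replicate 3. Genes of cisplatin transport and detoxification had a median of 0.06 (adjusted p = 0.591).

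**Figure D2:**
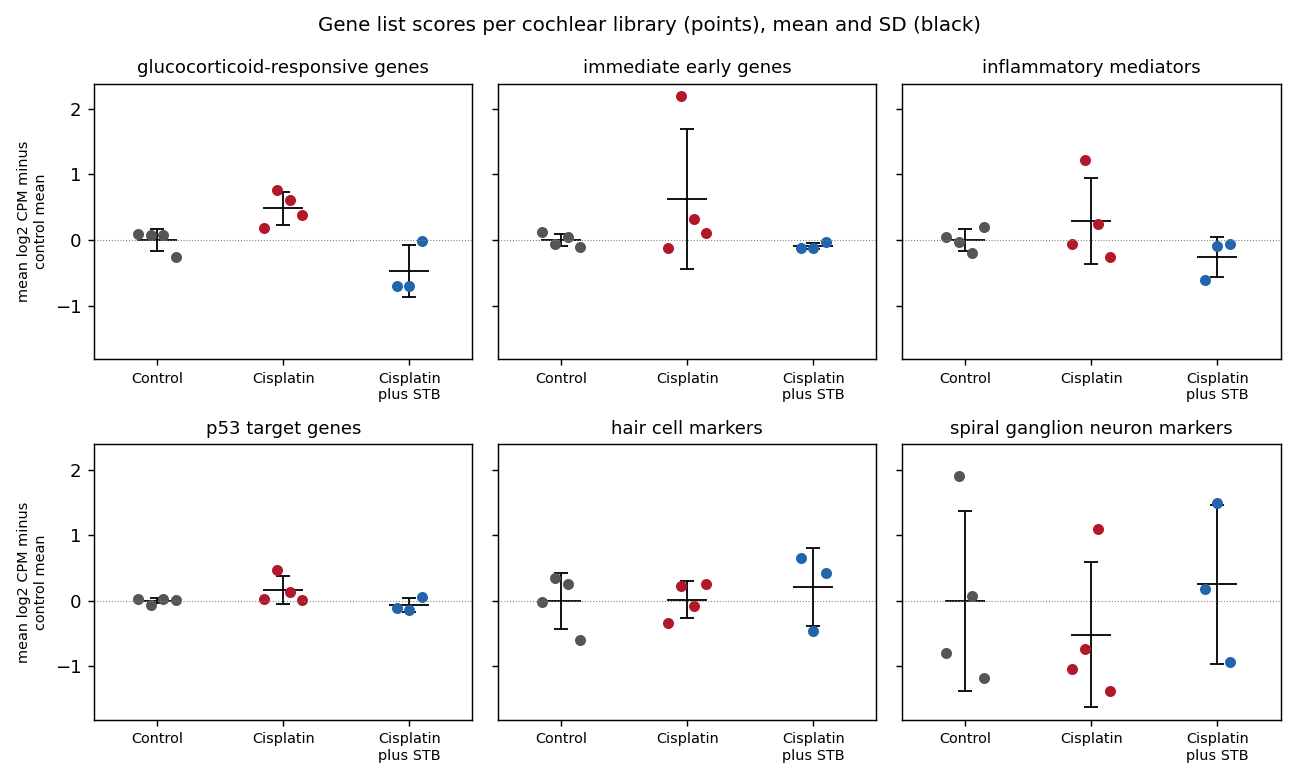
Scores of 6 gene lists in each library (mean log2 CPM of the members minus the control mean) for the control, cisplatin and cisplatin plus STB groups; points are libraries and bars give the mean and SD. The glucocorticoid-responsive score was 0.48 ± 0.25 after cisplatin and -0.47 ± 0.40 after the combined treatment, and cisplatin replicate 2 stood at 2.19 for immediate early genes.

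The combined treatment was then compared with cisplatin alone, the comparison that bears on STB. Col17a1, at positions 78278402 to 78355033 on the minus strand of its scaffold, rose from 5.77 ± 1.35 to 19 ± 4.71 CPM (SD, n = 4 and n = 3). Its log2 fold change was 1.72 (SE 0.23, edgeR adjusted p = 0.0473). Adap2, at positions 70848819 to 70875524 on the minus strand, fell from 185 ± 25.4 to 65.3 ± 14.2 CPM, a log2 fold change of -1.5 (SE 0.17, edgeR adjusted p = 0.0133). Wnk4, a kinase that regulates ion transport, at positions 94520826 to 94532548 on the plus strand of the same scaffold as Adap2, fell from 115 ± 10.6 to 56.4 ± 5.80 CPM, a log2 fold change of -1.03 (SE 0.14, edgeR adjusted p = 0.0499). These 3 were the genes called, and for each the libraries of both groups did not overlap. DESeq2 called 101 genes and limma-voom with quality weights 215, each including these 3. By contrast, edgeR called 0 when fitted to only the groups compared, and 0 with a replicate block (smallest edgeR adjusted p = 0.0594). With DESeq2 size factors or upper-quartile scaling in edgeR, Adap2 and Col17a1 were called and Wnk4 was not. With 2 surrogate variables, a fit added after the data were seen, Adap2 alone was called. At an unadjusted p under 0.05 edgeR gave 1389 genes, while other splits of these libraries gave 202 to 3007. Libraries of both groups did not overlap for 7.54% of genes, where the average over all splits is 5.71%. No gene was called without cisplatin replicate 3, cisplatin replicate 4 or combined replicate 1, where the smallest edgeR adjusted p was 0.0733, 0.0608 and 0.114. Adap2 alone was called without control replicate 1, control replicate 3, control replicate 4 or combined replicate 2. Adap2 and Wnk4 were called without control replicate 2, and Adap2 and Col17a1 without cisplatin replicate 2. These 3 were among 15 genes without cisplatin replicate 1 and among 23 without combined replicate 3.

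By camera 6 of 38 lists were called for the combined treatment against cisplatin, and 32 of 35 splits, the real one included, gave as many (highest other 18). Glucocorticoid-responsive genes were lower, with a median log2 fold change of -1.0 over 16 members (camera adjusted p = 2.97e-10; adjusted p = 0.296 with an estimated correlation; adjusted p = 0.0740 with fry). Adjusted over the list alone 11 of them fell and 0 rose, and 0 were called by edgeR over all genes. Among those that fell were Klf15, a transcription factor of amino acid metabolism (-0.92, SE 0.19), Hif3a, a hypoxia-inducible factor subunit (-2.37, SE 0.51), Glul, glutamine synthetase (-1.19, SE 0.27), and Klf9 (-1.38, SE 0.31). Glul was at 1549 ± 179 CPM in control, 2547 ± 657 CPM after cisplatin and 1120 ± 498 CPM after the combined treatment. The camera call was kept with any 1 library left out (adjusted p = 0.181 to 0.598 with an estimated correlation), and 7 members fell over the list alone without combined replicate 1. Circadian clock genes, which share Per1 with this list, had a median of -0.07 (camera adjusted p = 0.0839). Hlf, Per1 and Bhlhe41 fell over the list alone (log2 fold changes -0.83, -0.54 and -0.57), though none did without combined replicate 1. Over all genes their edgeR adjusted p was 0.279, 0.349 and 0.354.

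Immediate early genes (median -1.07, camera adjusted p = 0.000101; adjusted p = 0.896 with an estimated correlation) and inflammatory mediators (median -0.39, adjusted p = 0.00735; adjusted p = 0.831 with an estimated correlation) were also lower, with no member past the threshold over the list alone. Dusp1 had a log2 fold change of -0.81 (SE 0.23), Zfp36, an mRNA decay factor, of -1.67 (SE 0.59), Nr4a1, an orphan nuclear receptor, of -1.5 (SE 0.55) and Egr1, a zinc finger transcription factor, of -2.56 (SE 0.98). Among inflammatory mediators, Il1r1, the interleukin-1 receptor, stood at -0.77 (SE 0.23) and Nfkbia, the NF-kappa-B inhibitor, at -0.71 (SE 0.24). The inflammatory score was 1.22 in cisplatin replicate 2 and between -0.26 and 0.24 in the other cisplatin libraries. Without that library the median of immediate early genes was -0.20 (camera adjusted p = 0.0390; adjusted p = 0.598 with an estimated correlation), and the call of inflammatory mediators was lost without cisplatin replicate 2 (0.192) or combined replicate 1 (0.0566). Without cisplatin replicate 1, 10 immediate early genes fell over the list alone.

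The p53 target genes were lower (median -0.30, camera adjusted p = 0.0228; adjusted p = 0.402 with an estimated correlation). Sesn1 fell over the list alone (log2 fold change -1.11, SE 0.21, edgeR adjusted p = 0.00485 over the list and 0.205 over all genes), and Gadd45a stood at -1.02 (SE 0.30). The p53 call was lost without cisplatin replicate 2 (0.183). Antioxidant and NRF2 target genes had a median of -0.14 (camera adjusted p = 0.0222; adjusted p = 0.900 with an estimated correlation), with Fth1 at -0.68 (SE 0.21) and Sod2, the mitochondrial superoxide dismutase, at 0.37 (SE 0.12), and lost the call without cisplatin replicate 2 (0.280) or combined replicate 3 (0.277). Cell death machinery had a median of -0.14 (adjusted p = 0.0839; called without cisplatin replicate 4 (0.0489; adjusted p = 0.456 with an estimated correlation) or combined replicate 2 (0.0295; adjusted p = 0.437 with an estimated correlation); median -0.07 without combined replicate 3). Bcl2l1, which encodes the anti-apoptotic BCL-XL, fell over the list alone (log2 fold change -0.76, SE 0.19, edgeR adjusted p = 0.0423 over the list and 0.349 over all genes). It did not pass over the list without any 1 of control replicates 1 to 3, cisplatin replicate 3, cisplatin replicate 4, combined replicate 1 or combined replicate 2. Unfolded protein response genes had a median of 0.00 (camera adjusted p = 0.836), with 14 positive and 14 negative, and a median of -0.18 without combined replicate 3. They were called without combined replicate 2 (camera adjusted p = 0.0247, or 0.603 with an estimated correlation), a library with a score of -0.15. Their score was 0.03 and 0.35 in combined replicates 1 and 3, against a cisplatin mean of 0.06 ± 0.22. Sdf2l1 stood at 0.66 (SE 0.21), Hsp90b1, the chaperone GRP94, at 0.68 (SE 0.27) and Atf4 at -0.38 (SE 0.16). Interferon-stimulated genes had a median of 0.03 (adjusted p = 0.656).

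Spiral ganglion neuron markers were higher after the combined treatment than after cisplatin (median 0.74, camera adjusted p = 0.0128; adjusted p = 0.966 with an estimated correlation), with 27 of 30 positive and 0 past the edgeR threshold over the list alone. Prph, the intermediate filament peripherin, had a log2 fold change of 1.48 (SE 0.61), Ntrk2, the BDNF receptor, of 0.50 (SE 0.29) and Nefl, neurofilament light chain, of 1.16 (SE 0.77). The call was lost without cisplatin replicate 1 (0.0932), cisplatin replicate 2 (0.0685) or combined replicate 2 (0.570), and without combined replicate 2 the median was -0.26. Hair cell markers had a median of 0.25 (adjusted p = 0.188), with Pcdh15 at 0.61 (SE 0.28). They were called as higher without cisplatin replicate 4 (0.0186; adjusted p = 0.842 with an estimated correlation) or combined replicate 2 (9.34e-08; adjusted p = 0.437 with an estimated correlation), and had a median of -0.07 without combined replicate 1. Stria vascularis markers had a median of -0.03 (adjusted p = 0.786), with Pmel, a melanosome protein of intermediate cells, at -0.75 (SE 0.23). They were called without combined replicate 2 (camera adjusted p = 0.0254, or 0.608 with an estimated correlation), a library with a score of -0.33. Their score was 0.26 and 0.81 in combined replicates 1 and 3, above the cisplatin mean of 0.08 ± 0.88. Their median was -0.30 without combined replicate 3. Macrophage markers had a median of -0.16 (adjusted p = 0.188), or -0.03 without combined replicate 1. They were called without cisplatin replicate 4 (camera adjusted p = 0.000440, or 0.525 with an estimated correlation) or combined replicate 2 (0.00271, or 0.603 with an estimated correlation). Among them Cd163 fell over the list alone, from 8.62 ± 3.76 to 1.65 ± 0.343 CPM. Its log2 fold change was -2.38 (SE 0.39, edgeR adjusted p = 0.00107 over the list and 0.156 over all genes).

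The combined treatment was compared with control to ask what still differed from the untreated cochlea. The genes with the smallest p that were higher in all 3 combined libraries were Bco2, a carotenoid oxygenase (log2 fold change 0.60, SE 0.18), Thbs4, a thrombospondin (0.58, SE 0.18), Smim5 (0.99, SE 0.32), Mns1 (1.14, SE 0.38) and Col23a1, a transmembrane collagen (1.31, SE 0.44). Those lower were Wnk4 (-0.56, SE 0.14), Per1, a core clock gene (-0.52, SE 0.14), Prc1, a cytokinesis protein (-1.76, SE 0.47), Echdc2 (-0.71, SE 0.19) and Abtb2 (-0.42, SE 0.12). Smim5, Mns1 and Prc1 overlap a gene on the opposite strand and Col23a1 a gene on its own strand. Col17a1 had a log2 fold change of 0.04 (SE 0.23) and Adap2 of -0.49 (SE 0.16). No gene was called: edgeR, DESeq2 and limma-voom with quality weights each gave 0. By edgeR 165 genes had an unadjusted p under 0.05, where chance would give 769 and other splits of these libraries gave 158 to 1858. Libraries of both groups did not overlap for 2.41% of genes, where the average over all splits is 5.71%. The genes named above thus come from a comparison with fewer small p than chance would give. Without combined replicate 3 edgeR called 2 genes, of which Hoga1 has a symbol other than a LOC symbol.

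In this comparison 7 lists were called by camera, and 23 of 35 splits, the real one included, gave as many (highest other 13). Glucocorticoid-responsive genes (median log2 fold change -0.42, camera adjusted p = 3.40e-08; adjusted p = 0.513 with an estimated correlation) and endothelial markers (median -0.25, adjusted p = 6.01e-06; adjusted p = 0.685 with an estimated correlation) were lower and were called with any 1 library left out (adjusted p = 0.0968 to 0.981 and 0.464 to 0.981 with an estimated correlation). The glucocorticoid median was -0.21 without combined replicate 1 and the endothelial median -0.45 without combined replicate 2. The glucocorticoid score was -0.70 and -0.69 in combined replicates 1 and 2 but -0.01 in combined replicate 3. Per1 fell over the list alone (edgeR adjusted p = 0.0364 over the list and 0.999936 over all genes). It did not pass over the list without control replicates 1, 2 or 3, cisplatin replicates 1 or 3, or combined replicates 1 or 2. Without combined replicate 3, 7 members fell over the list alone. Vwf and Pecam1, which mark vessel endothelium, stood at -0.44 (SE 0.21) and -0.45 (SE 0.23). Interferon-stimulated genes (median -0.51, adjusted p = 0.000285), Schwann cell and peripheral myelin markers (median -0.20, adjusted p = 0.0206) and inflammatory mediators (median -0.18, adjusted p = 0.0346) were lower by camera. Cytosolic ribosomal proteins (median 0.07, adjusted p = 0.000285) and hair cell markers (median 0.26, adjusted p = 0.00737, 25 of 26 positive) were higher. Each of these 5 had an adjusted p = 0.846 with an estimated correlation. No member of these 5 lists passed over the list alone. The call was lost for interferon-stimulated genes without control replicate 4 (0.612) or combined replicate 2 (0.340), and for Schwann cell markers without control replicate 1 (0.883), control replicate 2 (0.0873), combined replicate 1 (0.0647) or combined replicate 3 (0.470). It was also lost for inflammatory mediators without control replicate 1 (0.0863), control replicate 4 (0.281), cisplatin replicate 4 (0.0533), combined replicate 1 (0.643) or combined replicate 3 (0.0769), for ribosomal proteins without control replicate 2 (0.867), control replicate 4 (0.281) or combined replicate 2 (0.856) and for hair cell markers without control replicate 4 (0.905), combined replicate 1 (0.760) or combined replicate 3 (0.518), each with its camera adjusted p. Spiral ganglion neuron markers had a median of -0.02 (adjusted p = 0.0959) and were called as higher without control replicate 2 (4.28e-08; adjusted p = 0.576 with an estimated correlation) or combined replicate 3 (4.03e-05; adjusted p = 0.919 with an estimated correlation). Their median was -1.07 without combined replicate 2.

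The return toward control was measured as the share of genes changed by cisplatin whose fold change for the combined treatment against cisplatin had the opposite sign. With the cisplatin libraries split, edgeR at an adjusted p under 0.05 gave 1 gene in 1 of the 6 assignments and none in the others, and it had the opposite sign (100%). Without control replicate 3 this share was 0, and without control replicate 4 no gene was left. With genes taken at an unadjusted p under 0.01, a mean of 346 genes per assignment, 81.4% had the opposite sign (75.2% to 86.4% over the single assignments). In simulated data without group differences the share was 50.4%. Its range, 46.5% to 53.4%, is over the means of 5 data sets, so these ranges are not of the same kind. Regroupings of the real libraries gave a wider range than the simulated data, 16.5% to 90.1% by limma-trend, where the real grouping gave 80.6%. Without the split, 336 genes were taken and 100% had the opposite sign, where the simulated value was 90.5%, since both comparisons share the cisplatin libraries. The covariance of the log2 fold changes across genes was -0.0817 with the split, against -0.00117 simulated, and -0.145 without it, against -0.0632 simulated. The unsplit correlation across genes was -0.80, and genes are not independent replicates. Col17a1 and Adap2 were among the genes with the smallest p in both comparisons that involve the cisplatin libraries.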

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

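The counts of other splits and the tests of cisplatin replicate 2 and of the neuron score were chosen only after the results were seen, while the adjustment for marker scores and the second glucocorticoid list were written down before their results were seen.

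In the control group, replicate 4 lay far from the others in the score of glucocorticoid-responsive genes (-0.26, others 0.08 to 0.10). In the cisplatin group, replicate 1 lay far from the others in Adap2 (log2 CPM 7.20, others 7.62 to 7.63) and in Wnk4 (log2 CPM 6.63, others 6.89 to 6.92). Of 86 groups of 4 libraries tested for such a gap, 3 passed the limit. Chance passes about 1 in 20 groups, here 4.3.

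Glucocorticoid-responsive genes, a list singled out of 38 after the results were seen, were higher after cisplatin (median log2 fold change 0.73, camera adjusted p = 0.667 with an estimated correlation). Without cisplatin replicate 2 that median was 0.47. They were lower after the combined treatment than after cisplatin (-1.0). Cisplatin replicate 2 as the whole cause is argued against by the median without it (-0.83, quartiles -1.10 to -0.20, camera adjusted p = 6.42e-10; adjusted p = 0.598 with an estimated correlation), and differing neuron, stria and Schwann content as the whole cause by the median with those marker scores as covariates (-0.96, quartiles -1.30 to -0.46, camera adjusted p = 1.13e-08; adjusted p = 0.830 with an estimated correlation, against 0.296 with all libraries and no covariates). A second glucocorticoid list with no shared member was lower too (median -0.27 over 24 genes, 21 negative, camera p = 1.56e-05, p = 0.0244 with an estimated correlation). Its median for cisplatin against control was 0.20 (camera p = 0.00456, p = 0.107 with an estimated correlation), or 0.13 without cisplatin replicate 2 (camera p = 0.0671). The second list was measured in the same libraries, so it is not independent support, and it was not put through the splits. Both comparisons share the cisplatin libraries with opposite sign, so opposite directions of either list arise in part with no effect. For the first list, 1 of the 35 splits of these libraries, the real one, gave a camera p as small for the combined treatment against cisplatin (minus log10 p 11.1, highest other 9.99). For cisplatin against control 1 of 35 did so (4.53, highest other 3.99). For the combined treatment against control 2 of 35 did so, the real one included (9.05, highest other 12.9). The first list was picked for its small p, so chance cannot be excluded. Glucocorticoid signalling that was higher with cisplatin and lower with the combined treatment stays open beside chance. So do hormone levels, handling, the hour of sampling and the content of cell types other than neuron, stria and Schwann, which were untested. Adipocyte markers, not among the covariates, had a median of -0.36 for the combined treatment against cisplatin, with 9 of 10 negative. Camera did not call them (adjusted p = 0.0839, or 0.694 with an estimated correlation).

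Immediate early genes were higher in the cisplatin group (camera adjusted p = 0.000567, or 0.907 with an estimated correlation). Both they and inflammatory mediators, not called against control (median 0.38), scored highest in cisplatin replicate 2 (immediate early score 2.19, inflammatory score 1.22). Without that library the median of immediate early genes for cisplatin against control was 0.16 in place of 0.95, and camera no longer called the list (adjusted p = 0.279). This is consistent with a state of that library alone. Its handling before RNA extraction and a stronger response of its donor stay open, as untested, since the labels give neither. Immediate early genes were still called without it as lower with the combined treatment than with cisplatin (median -0.20, against -1.07 with all libraries, adjusted p = 0.0390; adjusted p = 0.598 with an estimated correlation).

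Spiral ganglion neuron markers differed widely between libraries of a group, from -1.17 to 1.9 in control and from -1.38 to 1.10 after cisplatin. Groups accounted for 8.17% of the variance of this score, where 20% would be the mean share with no effect. This is consistent with a neuron content that differed from library to library, as dissection could give. A loss of neurons with cisplatin stays open, as untested, since no cell counts were analysed here.

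For cisplatin against control, 33 of the 35 splits of the libraries gave as many lists as the real one (5, highest other 13). All such counts in this paragraph include the real grouping itself. Between the combined treatment and cisplatin 2 of 35 gave as many genes (3, highest other 8, from a split that put cisplatin replicates 2, 3 and 4 against the rest) and 32 as many lists (6, highest other 18). Between the combined treatment and control 23 gave as many lists (7, highest other 13). For the return toward control 5 of 100 regroupings, the real one included, gave a share as large by limma-trend (80.6%, highest other 90.1%). Chance cannot be excluded for these list counts, for the 3 genes or for the return. In the other comparisons edgeR called 0 genes, so that all 35 splits were bound to give as many (highest other 0 for cisplatin against control and 1 for the combined treatment against control), which says nothing about chance. At an unadjusted p under 0.05 edgeR gave 1494 and 165 genes there (other splits 181 to 1849 and 158 to 1858), DESeq2 called 33 and 0, and limma-voom with quality weights 3 and 0.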

How the results depend on the processing

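The fit with 2 surrogate variables was the alternative chosen only after the data were seen. Of 4204 log2 values under the alternatives 4003 kept their direction and side of the threshold, 74 newly passed it, 65 no longer did and 62 changed sign. Few of these values passed the threshold with all libraries: 3 genes, and 5, 6 and 7 lists in the 3 comparisons. Most had no call to lose, so the 4003 does not measure how robust the calls were. Cnpy2 kept its sign with any 1 library left out (log2 fold change 0.18 to 0.29 for cisplatin against control, -0.22 to -0.045 for the combined treatment against cisplatin). The cause of the changes below was not tested, except that leaving out a library lowers the number of samples. For cisplatin against control, genes called were 0 by edgeR (1494 at an unadjusted p under 0.05), 33 by DESeq2, 3 by limma-voom with quality weights, 1 with no low-count filter and 0 to 7 with 1 library left out. Lists called were 5, 8 with a replicate block, 0 with an estimated correlation, 0 by fry and 1 to 10 with 1 library left out. With the combined treatment against cisplatin, genes called were 3, 101 by DESeq2, 215 by limma-voom, 0 with only the groups compared, 0 with a block, 1 with 2 surrogate variables, 0 at an adjusted p under 0.01 and 0 to 23 with 1 library left out. Lists called were 6, 14 with a block, 0 with an estimated correlation, 0 by fry and 2 to 18 with 1 library left out. Against control, the combined treatment with 1 library left out gave 0 to 2 genes and 4 to 11 lists (0 and 7 with all libraries, and 0 lists with an estimated correlation and 0 by fry). The return toward control was 100% with adjusted calls, which rest on 1 gene in 1 assignment, and 0 to 100% with 1 control or combined library left out. It had no such value without control replicate 4, nor without the split, since no gene was called. At an unadjusted p under 0.01 it was 81.4%, and 73.9% to 85.9% with 1 control or combined library left out. Leaving out a cisplatin library was not run, since the measure splits these 4 into pairs. Depth limits what was tested: 6097 genes of low count were not.

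These values changed sign. The Cnpy3 log2 fold change, cisplatin against control, was -0.027 with upper-quartile scaling, -0.0081 with a block, -0.073 with 2 surrogate variables and -0.12 to 0.12 with 1 library left out, and that of Rsad2 0.31 by limma-voom. With 1 library left out, the Tyrp1 log2 fold change, cisplatin against control, ranged from -0.0026 to 1.69. Medians that changed sign in these fits were those of the unfolded protein response (-0.0023 to 0.11), interferon-stimulated genes (-0.75 to 0.054), hair cell markers (-0.14 to 0.092), neuron markers (-1.52 to 0.45), macrophage markers (-0.029 to 0.24), cisplatin transport (-0.064 to 0.12) and stria markers (-0.11 to 0.34). Between the combined treatment and cisplatin, Cnpy3 was -0.016 with a block (-0.059 to 0.16 with 1 library left out), the unfolded protein response -0.0066 with DESeq2 size factors (-0.18 to 0.13), cisplatin transport -0.0058 with DESeq2 size factors, -0.0097 with no filter and -0.072 with a block (-0.077 to 0.023), stria markers 0.041 with a block (-0.30 to 0.29), interferon-stimulated genes -0.40 to 0.24, hair cell markers -0.066 to 0.54 and neuron markers -0.26 to 1.78 with 1 library left out. Between the combined treatment and control, Cnpy3 was -0.024 with a block (-0.033 to 0.15) and neuron markers 0.096 (-1.07 to 1.18), while interferon-stimulated genes (-0.83 to 0.053), ribosomal proteins (-0.016 to 0.19), Prph (-0.16 to 1.13), the Gata3 log2 fold change, cisplatin_plus_STB against control (-0.0031 to 0.37) and the Rbfox3 log2 fold change, cisplatin_plus_STB against control (-2.35 to 0.90) changed sign with 1 library left out. The replicate numbers did not pair the libraries: correlations of libraries with the same number were 0.09, -0.10, -0.04, 0.31 for cisplatin and control, 0.13, 0.05, -0.31 for the combined treatment and cisplatin, and 0.07, 0.36, -0.01 for the combined treatment and control.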

Other observations

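The genes in this part were singled out only after their values were seen, from lists fixed before.

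With the combined treatment, 3 proliferation genes fell against cisplatin over the list alone: Tpx2, a spindle assembly factor (log2 fold change -1.10, SE 0.24, edgeR adjusted p = 0.0108 over the list), Prc1, a cytokinesis protein (-1.78, SE 0.47, edgeR adjusted p = 0.0205 over the list), and Rrm2, a subunit of ribonucleotide reductase (-1.84, SE 0.60, edgeR adjusted p = 0.0487 over the list). Over all genes the edgeR adjusted p of these 3 was 0.272, 0.353 and 0.414. Mcm2, a subunit of the replicative helicase, rose (0.69, SE 0.23, edgeR adjusted p = 0.0487 over the list and 0.423 over all genes). The list as a whole was not called (median -0.23 over 18 genes, camera adjusted p = 0.0986), but was called without combined replicate 2 (0.0489; adjusted p = 0.437 with an estimated correlation). No member passed over the list alone without combined replicate 1. Without control replicate 2, control replicate 3 or control replicate 4, 2 members fell and none rose, and without cisplatin replicate 1, cisplatin replicate 2 or cisplatin replicate 3, 3 fell and none rose. Without cisplatin replicate 4 or combined replicate 3, 1 fell and none rose. The median was -0.05 without cisplatin replicate 2 and -0.10 without combined replicate 3.

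Cisplatin transport and detoxification was not called for the combined treatment against cisplatin (median 0.01, camera adjusted p = 0.681). The score of stria vascularis markers ran from -0.85 in cisplatin replicate 2 to 0.96 in cisplatin replicate 3, and that of Schwann cell and peripheral myelin markers was -1.04 in cisplatin replicate 4 and between -0.14 and 0.35 in the other cisplatin libraries.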
